A study of Mus musculus with 12 samples.

How the data were processed

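RNA sequencing was done on whole liver, with total RNA extracted in ISOGEN, per the labels' protocols. The 12 libraries came from male mice aged 7 to 10 weeks. Control mice carried Fbxl5 alleles flanked by loxP sites, and FBXL5ΔDC mice carried the same alleles with Cre recombinase driven by the Cd11c (Itgax) promoter, which is active mainly in dendritic cells. FBXL5 is the iron-sensing subunit of a ubiquitin ligase that degrades the iron regulatory protein IRP2. Livers were taken from untreated mice, here called 0 h, or 6 h after an injection of acetaminophen, a drug that injures the liver when overdosed. The labels gave a dose of 300 or 500 mg/kg without saying which dose these mice received. Mice to be injected were fasted for 16 h and had food again afterwards, per the labels' protocols, and whether the 0 h mice were fasted was not stated. The labels call each replicate by its group and a number, and do not say how littermates or cages were spread over groups. The p-values therefore measured only the spread between these samples.

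Reads were trimmed with Trim Galore 0.6.6 and aligned with HISAT2 2.2.1 to the mouse build mm10, per the submitters' processing notes. The values were estimated counts per gene, deposited without normalisation in 1 table of 12 libraries, and the counting program and its strand setting were not given in the sources used here. All values were whole numbers, but low values piled up at multiples of 4. Between 26.5% and 28.5% of the values from 1 to 40 were multiples of 4 in each library, against 25% for an even spread. Genes were 1.55 to 1.84 times as frequent at 4, 8, 12 and 16 as at the neighbouring values. What causes this was not tested, and most low values were not multiples of 4, so the number of sequenced fragments behind a count is not known. The plan written earlier had taken the values as raw counts, and the test was kept because the values were already whole. The unit made no difference to rounding.

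The table held 55401 genes, of which 26840 had 0 counts in every library. Identifiers matched the GENCODE vM21 annotation of GRCm38 for 98.1% of genes with their version number and for 99.5% without it. A symbol shared with another gene was found for 217 genes, which were kept apart by identifier. No library was a copy of another. The lowest value of chi-square per degree of freedom between any pair of libraries, with counts divided by 4, was 26.0. An exact copy would give 0, and a repeat sampling of 1 library about 1 if a fragment gave 4 counts. Total counts ran from 67173096 to 72512319 per library.

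Genes were filtered with filterByExpr by group, libraries were scaled with TMM factors (range 0.855 to 1.14), and 17585 genes were tested. A quasi-likelihood model with robust dispersions was fitted in edgeR 4.0.16 under R 4.3.3, with 1 coefficient for each of the 4 groups and 8 residual degrees of freedom. The common dispersion was 0.153, a biological coefficient of variation of 0.391. The 5 contrasts were 6 h minus 0 h in control livers, 6 h minus 0 h in FBXL5ΔDC livers, FBXL5ΔDC minus control at 0 h, FBXL5ΔDC minus control at 6 h, and the difference between the responses, called the interaction. Changes were called at an adjusted p below 0.05 after Benjamini-Hochberg correction over all tested genes of a contrast. Abundances are given as CPM (counts scaled to the library size) with TMM-scaled library sizes, as mean ± SD, and log2 CPM used a prior count of 2. Log2 changes are those of the model, with their standard error (SE). A group whose mean was under 12 counts per library, a cautious choice that equals 3 fragments if each gave 4 counts, was called under the detection floor. The floor was 0.161 CPM in both control groups, 0.176 CPM in FBXL5ΔDC at 0 h and 0.187 CPM in FBXL5ΔDC at 6 h, and it covers counting error only.

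Gene lists were written from general knowledge of liver biology before the data were examined, as were the contrasts, the tests and most of the alternatives. The 35 lists covered hepatocyte zones, drug metabolism, stress responses, iron and ferroptosis, lipid, bile acid and glucose metabolism, plasma proteins, cell types, cell death, cell cycle, the circadian clock and mitochondrially encoded transcripts. Each list was tested against all other genes with camera in limma 3.58.1 with an inter-gene correlation of 0.01. Adjusted p-values of camera were corrected over the 35 lists of a contrast. The same test with an estimated correlation asks more of a list when its members vary together between libraries. Its adjusted p is given where a list was called with the fixed correlation only. Numbers of members that rose or fell are given over all tested genes and again with p-values adjusted over the list alone. The rotation test fry was an alternative that asks whether members moved one way.

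Genes were named by a rule set before the data were examined. Fbxl5 and Itgax were always named. Each contrast also gave up to 10 rises and 10 falls with the largest changes among called genes, with a minimum mean of 2 log2 CPM for the acetaminophen responses and 0 log2 CPM for the other contrasts. Outside the interaction, all libraries of one group had to lie above all libraries of the other. Predicted gene models and pseudogenes were counted but not named. Each list gave the 4 members with the smallest p and the 2 members with the highest CPM. A gene named in one contrast was also followed in the others. In the contrast without called genes, the 5 smallest p-values of each direction were named.

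The alternatives were other size factors (median of ratios, upper quartile), other filters (none, or 1 CPM in 3 libraries with 10 counts on average), DESeq2 1.42.0, limma-voom with sample quality weights, only the groups compared, a replicate block, non-robust dispersions and each library left out in turn. Division of the counts by 4 and removal of mitochondrial genes were added after the table was seen. The scripts were tested on simulated data with 200 changed genes, drawn from the means and sizes of the real libraries. Each gene had 1 dispersion shared by all groups, so unequal spread between groups was not simulated. At a 2-fold change, 34% of changed genes were recovered for acetaminophen in control livers, 50% for acetaminophen in FBXL5ΔDC livers, 32% for genotype at 0 h, 40% for genotype at 6 h and 8% for the interaction. At a 4-fold change the shares were 78%, 84%, 79%, 84% and 66%. False calls numbered between 1 and 7. A simulated list changed 1.5-fold had an adjusted p of 5.67e-10 in camera and of 0.00247 with an estimated correlation, and 0 unchanged lists were called. Simulated genes varied independently, so false calls of lists whose members vary together were not covered. In regroupings of the real treated libraries, given below, camera with the fixed correlation called up to 19 lists. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.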

Results

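Whole-liver RNA was sequenced in 12 libraries, 3 from each of 4 groups. The groups were untreated control livers (0 h), untreated FBXL5ΔDC livers (0 h), and livers of both genotypes taken 6 h after acetaminophen. Total counts were 70.2 ± 1.32 M (M for mega, mean ± SD, n = 3) in control livers at 0 h and 69.9 ± 1.04 M at 6 h. In FBXL5ΔDC livers they were 71.2 ± 1.21 M at 0 h and 70.0 ± 2.48 M at 6 h. Between 19203 and 21405 genes were detected per library, and the albumin gene Alb was the most abundant gene in each. The 10 most abundant genes held 15.02% to 21.3% of the counts. Mitochondrially encoded genes held 6.34 ± 0.886% and 6.54 ± 0.270% of counts at 0 h in control and FBXL5ΔDC livers, and 6.60 ± 0.390% and 9.19 ± 0.245% at 6 h. All abundances below are mean ± SD with n = 3 per group, and adjusted p-values of genes are those of edgeR.

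Fbxl5 (ENSMUSG00000039753.16), the gene deleted in Cd11c-expressing cells, lies on GRCm38 chromosome 5 from 43744615 to 43821638. Its abundance in whole liver was 20.1 ± 2.27 CPM in control and 17.2 ± 5.99 CPM in FBXL5ΔDC livers at 0 h, a log2 difference of −0.23 (SE 0.27, edgeR adjusted p = 1). At 6 h it was 15.8 ± 3.01 CPM in control and 18.6 ± 5.25 CPM in FBXL5ΔDC livers, a log2 difference of 0.23 (SE 0.27, edgeR adjusted p = 0.672). Acetaminophen did not change Fbxl5 detectably in control livers (log2 −0.34, edgeR adjusted p = 0.499) or FBXL5ΔDC livers (log2 0.12, edgeR adjusted p = 0.797). Itgax (ENSMUSG00000030789.9, chromosome 7 from 128129547 to 128150657) encodes CD11c and marks the cells in which Cre is made. Its abundance was below the detection floor at 0 h, with 0.158 ± 0.190 CPM in control and 0.114 ± 0.139 CPM in FBXL5ΔDC livers. At 6 h Itgax reached 0.372 ± 0.224 and 0.414 ± 0.232 CPM, without a genotype difference (log2 0.15, edgeR adjusted p = 0.968). Gene totals of whole liver, in which these cells are rare, thus did not show whether the deletion took place, and the genotypes are those of the labels.

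The largest axis of variation followed acetaminophen and separated the treated groups unequally. The first principal component held 39.8% of the variance and the second held 10.4%. Untreated libraries of both genotypes lay between −67.0 and −57.5 on the first component. The treated FBXL5ΔDC libraries lay at 97.7, 107.4 and 103.6, whereas treated control replicates 1 and 2 lay at −9.46 and −8.18 and replicate 3 at 86.8. Control replicate 3 also stood apart in single genes. Krt8, an epithelial keratin induced in injured hepatocytes, was at 519, 377 and 4056 CPM in the 3 treated control livers, against 3494 ± 366 CPM in treated FBXL5ΔDC livers. Cyp7a1, the first enzyme of bile acid synthesis, was at 106, 82.0 and 2.30 CPM in treated control livers and at 0.519 ± 0.453 CPM in treated FBXL5ΔDC livers. The median SD of log2 CPM across genes was 0.426 in treated control livers, 0.307 in treated FBXL5ΔDC livers, 0.250 in untreated control livers and 0.216 in untreated FBXL5ΔDC livers.

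**Figure D1:**
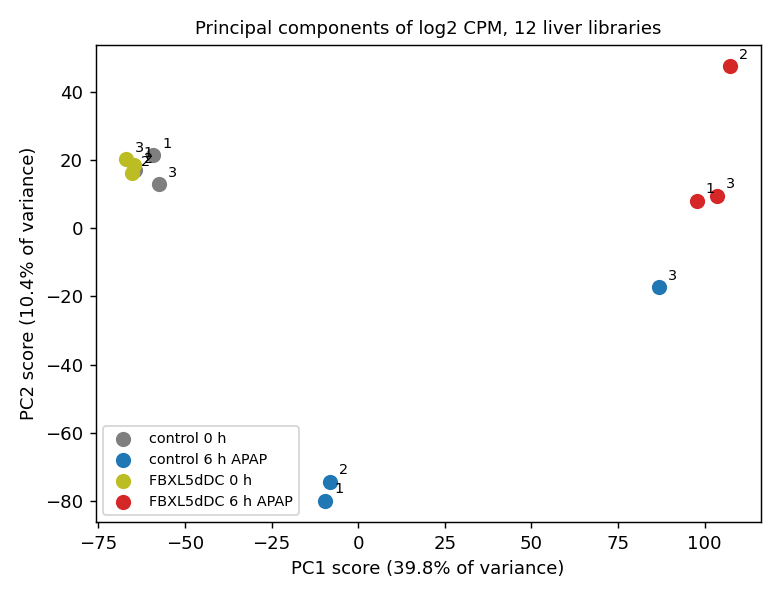
Scores of the 12 libraries on the first 2 principal components of log2 CPM, with 1 point per library coloured by group and numbered by replicate. Treated control replicate 3 (86.8 on the first component) lay near the treated FBXL5ΔDC libraries (97.7 to 107.4) and away from replicates 1 and 2 (−9.46 and −8.18).

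In control livers, acetaminophen raised stress-induced transcription factors, antioxidant enzymes and chaperones. Atf3 (ENSMUSG00000026628.13, chromosome 1 from 191170296 to 191218039), a transcription factor made under many kinds of stress, rose from 1.18 ± 0.658 to 557 ± 130 CPM (log2 8.88, SE 0.92, edgeR adjusted p = 6.16e-04). Hmox1 (ENSMUSG00000005413.8, chromosome 8 from 75093621 to 75100589), which degrades heme, rose from 13.5 ± 2.16 to 579 ± 505 CPM (log2 5.43, SE 0.63, edgeR adjusted p = 8.72e-04). Srxn1, which repairs oxidised peroxiredoxins, rose from 62.1 ± 1.59 to 1380 ± 654 CPM (log2 4.47, SE 0.28, edgeR adjusted p = 1.91e-05). Ddit3 (ENSMUSG00000025408.15, chromosome 10 from 127290774 to 127296288), which encodes the proapoptotic factor CHOP of the unfolded protein response, rose from 6.45 ± 2.48 to 89.3 ± 29.9 CPM (log2 3.79, SE 0.37, edgeR adjusted p = 1.79e-04). Its locus overlaps Mars on the other strand, and how the counting treated strands was not given in the sources used here. Dnajb1 (ENSMUSG00000005483.10, chromosome 8 from 83608193 to 83612653), a co-chaperone of HSP70, rose from 44.8 ± 16.5 to 554 ± 346 CPM (log2 3.63, SE 0.58, edgeR adjusted p = 0.00461). The chaperone gene Hspa1a rose from 32.5 ± 22.0 to 799 ± 648 CPM (log2 4.62, edgeR adjusted p = 0.0412), but it is nearly identical to Hspa1b, so that the split of counts between the pair is uncertain.

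Whole programmes moved with these genes. Of 22 immediate early genes, 17 rose over all genes tested and 20 when adjusted over the list alone, with a median log2 change of 3.95 (camera adjusted p = 1.3e-30, and 0.0479 with an estimated correlation). Klf6, Egr1, Dusp5 and Jun were among them, and Jun rose from 24.8 ± 6.32 to 391 ± 97.8 CPM (log2 3.98, edgeR adjusted p = 2.92e-04). Of 25 targets of the antioxidant factor NRF2 and glutathione synthesis genes, 17 rose and 1 fell by either adjustment (median log2 1.35, camera adjusted p = 5.37e-22, and 0.0462 with an estimated correlation). Gclc, which makes the first step of glutathione synthesis, rose from 381 ± 80.3 to 2363 ± 1174 CPM (log2 2.63, edgeR adjusted p = 2.92e-04). The cystine importer Slc7a11 went from below the floor to 7.06 ± 5.38 CPM, at least 43.7-fold above the floor (edgeR adjusted p = 0.00107). Of 23 genes of the integrated stress and unfolded protein response, 12 rose over all genes, and 14 rose and 2 fell when adjusted over the list alone (median log2 1.06, camera adjusted p = 7.91e-12, and 0.0462 with an estimated correlation). Chac1, which breaks down glutathione, rose from 0.879 ± 0.205 to 23.2 ± 7.66 CPM (log2 4.72, edgeR adjusted p = 2.21e-04). Of 18 heat shock genes, 12 rose over all genes and 14 over the list alone (median log2 1.42, camera adjusted p = 1.83e-12, but 0.149 with an estimated correlation). With 1 library left out, 5 to 15 heat shock genes rose (median log2 0.99 to 1.74), and 11 to 16 NRF2 and glutathione genes rose.

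Among p53 targets, 6 of 20 rose and 1 fell over all genes, and 8 rose and 1 fell over the list alone (median log2 0.98, camera adjusted p = 7.73e-05, but 0.0839 with an estimated correlation). Gadd45a, a growth arrest gene, rose from 0.922 ± 0.252 to 46.6 ± 17.5 CPM (log2 5.66, edgeR adjusted p = 3.15e-04). Of 19 genes of ferroptosis, an iron-dependent form of cell death, 8 rose and 3 fell over all genes, and 10 rose and 4 fell over the list alone (median log2 0.63, camera adjusted p = 0.00181, but 0.181 with an estimated correlation). Of 30 cell death genes, 5 rose and 1 fell, and 6 rose and 2 fell over the list alone (median log2 0.32, camera adjusted p = 0.0208, but 0.181 with an estimated correlation). Of 32 iron genes, 6 rose and 2 fell, and 9 rose and 2 fell over the list alone (median log2 0.33, camera adjusted p = 0.0489, but 0.181 with an estimated correlation). The transferrin receptor gene Tfrc, which brings iron into cells, rose from 23.03 ± 2.26 to 51.0 ± 18.5 CPM (log2 1.15, edgeR adjusted p = 0.00773). The ferritin genes Fth1 (log2 0.81, edgeR adjusted p = 0.0383) and Ftl1 (log2 0.61, edgeR adjusted p = 0.0348), which encode the iron store, rose as well. When any 1 library was left out, 3 to 7 p53 targets (median log2 0.55 to 1.12), 2 to 6 cell death genes (0.09 to 0.38) and 3 to 7 iron genes (0.13 to 0.33) rose. For ferroptosis the values were 6 to 10 genes and medians of 0.48 to 0.96.

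Genes of hepatocytes around the central vein, where acetaminophen is activated, fell in control livers. Glul (ENSMUSG00000026473.16, chromosome 1 from 153899944 to 153909723), which encodes glutamine synthetase and is restricted to those cells, fell from 556 ± 36.2 to 99.03 ± 45.2 CPM (log2 −2.49, SE 0.27, edgeR adjusted p = 2.57e-04). The glutamate transporter gene Slc1a2 fell from 142 ± 9.89 to 8.15 ± 6.13 CPM (log2 −4.12, SE 0.72, edgeR adjusted p = 0.00730). Cyp2e1 (ENSMUSG00000025479.9, chromosome 7 from 140763739 to 140774987), which turns acetaminophen into its toxic metabolite, fell from 8221 ± 1361 to 3511 ± 1007 CPM (log2 −1.23, SE 0.25, edgeR adjusted p = 0.00878). Of 25 pericentral genes, 10 fell and 1 rose over all genes, and 18 fell and 1 rose over the list alone (median log2 −1.13, camera adjusted p = 2.16e-15, but 0.0563 with an estimated correlation). Of 24 periportal genes, 1 rose and 1 fell by either adjustment, and the list was not called (median log2 0.16, camera adjusted p = 0.445).

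Fatty acid oxidation, drug and bile acid genes fell beside them. Of 30 PPARα targets and fatty acid oxidation genes, 15 fell over all genes and 18 over the list alone (median log2 −0.69, camera adjusted p = 8.51e-15, but 0.122 with an estimated correlation). Of 20 phase 1 drug-metabolising enzymes, 4 fell over all genes, and 12 fell and 2 rose over the list alone (median log2 −0.56, camera adjusted p = 1.12e-04, but 0.0632 with an estimated correlation). For genes that conjugate and export acetaminophen, 3 of 20 fell, and 5 over the list alone (median log2 −0.29, camera adjusted p = 0.00181, but 0.174 with an estimated correlation). Of 24 bile acid genes, 7 fell and 2 rose, and 14 fell and 3 rose over the list alone (median log2 −0.55, camera adjusted p = 1.32e-04, but 0.0632 with an estimated correlation). Cyp8b1, which sets the bile acid mixture, fell from 671 ± 254 to 199 ± 63.5 CPM (log2 −1.76, edgeR adjusted p = 0.00303). Of 24 cholesterol synthesis genes, 5 fell, and 6 over the list alone (median log2 −0.22, camera adjusted p = 0.0130, but 0.491 with an estimated correlation). Hmgcs1, an early enzyme of that pathway, fell from 102 ± 7.19 to 35.7 ± 3.96 CPM (log2 −1.52, SE 0.12, edgeR adjusted p = 4.2e-05). Of 33 hepatocyte identity genes, 3 fell, and 1 over the list alone (median log2 −0.14, camera adjusted p = 0.0296, but 0.290 with an estimated correlation). Over libraries left out, 10 to 17 PPARα, 2 to 7 phase 1, 4 to 9 bile acid, 1 to 4 conjugation and 1 to 4 cholesterol genes fell. For hepatocyte identity 1 to 3 genes fell, with medians of −0.21 to −0.10. The cholesterol median then ran from −0.31 to 0.01, so its fall was not settled.

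Immune genes rose less evenly. Of 32 cytokines, chemokines and adhesion genes, 7 rose and 1 fell, and 15 rose and 1 fell over the list alone (median log2 1.58, camera adjusted p = 6.42e-07, but 0.0632 with an estimated correlation). Csf1, a growth factor of macrophages, rose from 3.63 ± 0.236 to 13.1 ± 2.50 CPM (log2 1.85, edgeR adjusted p = 1.28e-04). Of 25 Kupffer cell genes, 4 rose by either adjustment (median log2 0.42, camera adjusted p = 8.12e-04, but 0.181 with an estimated correlation). Of 32 interferon-stimulated genes, 5 rose, and 8 over the list alone (median log2 0.53, camera adjusted p = 8.4e-04, but 0.326 with an estimated correlation). For monocytes and infiltrating macrophages, 3 of 24 markers rose by either adjustment (median log2 0.95, camera adjusted p = 0.00181, but 0.149 with an estimated correlation). For neutrophils, 2 of 15 markers rose, and 6 over the list alone (median log2 1.83, camera adjusted p = 0.00377, but 0.0839 with an estimated correlation). S100a9, a calcium-binding protein of neutrophils, went from below the floor to 0.808 ± 0.0914 CPM, at least 5.01-fold above the floor (edgeR adjusted p = 0.00676). Of 30 acute phase protein genes, 5 rose, and 6 over the list alone (median log2 0.29, camera adjusted p = 0.0116, but 0.491 with an estimated correlation). The numbers hung on single libraries, and leaving them out gave 1 to 11 cytokine, 1 to 4 Kupffer cell, 1 to 9 interferon-stimulated, 1 to 3 monocyte, 1 to 3 neutrophil and 1 to 5 acute phase genes.

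Control livers at 6 h were compared with control livers at 0 h to ask how acetaminophen acts when FBXL5 is intact. The edgeR test called 1118 genes higher and 739 lower, of which 610 and 264 changed at least 2-fold. By unadjusted p, 4346 genes were below 0.05, and 28.7% of genes had libraries of the treated group all above or all below the untreated ones, against 10% by chance. Upper quartile scaling gave 911 higher and 938 lower, or 50.7% lower in place of 39.8%, so the balance between rises and falls was not settled. DESeq2 called 1687 higher and 1196 lower, a fit to the 2 groups alone called 235 and 167, and leaving out any 1 untreated control library left 449 to 562 higher and 314 to 459 lower. Fasting of the untreated mice was not stated, so that feeding and handling may have been part of the comparison.

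**Figure D2:**
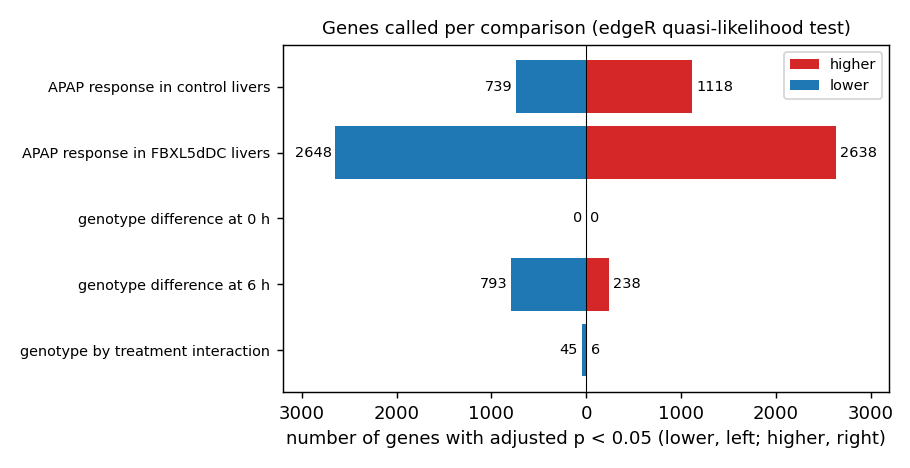
Genes called higher (right) and lower (left) in each contrast by edgeR at an adjusted p below 0.05, with numbers of genes on the horizontal axis. For acetaminophen 1857 genes were called in control and 5286 in FBXL5ΔDC livers, and for genotype 0 at 0 h and 1031 at 6 h. Numbers called depend on the spread within groups and on the fit, and do not measure the size of a change.

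In FBXL5ΔDC livers, acetaminophen lowered pericentral genes and raised genes such as Hbegf and Cxcl1. Cyp2c38 (ENSMUSG00000032808.2, chromosome 19 from 39389556 to 39463075), a pericentral cytochrome P450, fell from 69.8 ± 20.3 to 1.74 ± 0.247 CPM (log2 −5.32, SE 0.27, edgeR adjusted p = 1.08e-06). Oat (ENSMUSG00000030934.9, chromosome 7 from 132557478 to 132576398), which breaks down ornithine in the same cells, fell from 994 ± 139 to 36.3 ± 7.34 CPM (log2 −4.78, SE 0.38, edgeR adjusted p = 2.35e-05). Cyp2e1 fell from 9097 ± 401 to 843 ± 292 CPM (log2 −3.43, SE 0.27, edgeR adjusted p = 1.57e-05), and Glul fell from 669 ± 52.8 to 125 ± 13.6 CPM. Hbegf (ENSMUSG00000024486.6, chromosome 18 from 36504927 to 36515805), a growth factor of injured epithelia, rose from 0.429 ± 0.0998 to 51.7 ± 48.4 CPM (log2 6.91, SE 1.07, edgeR adjusted p = 0.00131). Cxcl1, which attracts neutrophils, rose from 0.468 ± 0.269 to 59.4 ± 12.5 CPM (log2 6.98, SE 1.33, edgeR adjusted p = 0.00402).

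Of 25 pericentral genes, 22 fell over all genes and 23 over the list alone (median log2 −2.82, camera adjusted p = 4.45e-33, and 0.0256 with an estimated correlation). Phase 1 enzymes fell too, with 12 of 20 lower and 1 higher over all genes, and 13 lower and 1 higher over the list alone (median log2 −0.94, camera adjusted p = 1.82e-08, and 0.0256 with an estimated correlation). Tbx3, a transcription factor of pericentral hepatocytes, fell from 35.7 ± 6.17 to 0.658 ± 0.0243 CPM (log2 −5.76, edgeR adjusted p = 5.39e-04), and Tbx3os1 overlaps it on the other strand. Ppp1r3b, which promotes glycogen synthesis, fell from 209.7 ± 46.6 to 5.08 ± 1.60 CPM (log2 −5.37, edgeR adjusted p = 0.00153). Of 24 bile acid genes, 16 fell and 3 rose, and 17 fell and 3 rose over the list alone (median log2 −0.83, camera adjusted p = 5.28e-06, but 0.0733 with an estimated correlation). Of 20 conjugation and export genes, 9 fell, and 10 over the list alone (median log2 −0.49, camera adjusted p = 5.97e-04, but 0.186 with an estimated correlation). Periportal genes went the other way, with 9 of 24 higher and 1 lower over all genes and 11 higher and 1 lower over the list alone (median log2 0.45, camera adjusted p = 0.00291, but 0.209 with an estimated correlation). Cyp2f2, a periportal cytochrome P450, rose from 936 ± 104 to 1535 ± 119 CPM (log2 0.71, edgeR adjusted p = 0.00135), and 5 to 8 periportal genes rose with 1 library left out.

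Antioxidant and immediate early genes rose in this genotype as well. Of 22 immediate early genes, 19 rose over all genes and 20 over the list alone (median log2 4.01, camera adjusted p = 7.18e-19, but 0.0884 with an estimated correlation). Of 25 NRF2 and glutathione genes, 16 rose and 1 fell by either adjustment (median log2 1.26, camera adjusted p = 5.03e-10, but 0.111 with an estimated correlation). Hmox1 rose from 12.9 ± 3.23 to 1071 ± 417 CPM (log2 6.37, edgeR adjusted p = 1.62e-04), and Srxn1 rose from 54.7 ± 2.88 to 1591 ± 210 CPM (log2 4.86, edgeR adjusted p = 4.37e-06). Slc7a11 rose from below the floor to 1.15 ± 0.775 CPM, at least 6.53-fold above the floor (edgeR adjusted p = 0.00142). Of 20 p53 targets, 9 rose and 1 fell, and 9 rose and 3 fell over the list alone (median log2 1.02, camera adjusted p = 0.00369, but 0.198 with an estimated correlation). Of 30 cell death genes, 12 rose and 3 fell, and 13 rose and 4 fell over the list alone (median log2 0.60, camera adjusted p = 0.00587, but 0.186 with an estimated correlation). Of 19 ferroptosis genes, 8 rose and 3 fell by either adjustment (median log2 0.46, camera adjusted p = 0.00293, but 0.230 with an estimated correlation). The zinc and iron importer gene Slc39a14 rose from 107 ± 16.5 to 790 ± 264 CPM (log2 2.88, edgeR adjusted p = 0.00117). Ireb2, which encodes the FBXL5 substrate IRP2, fell from 86.4 ± 2.33 to 40.4 ± 8.60 CPM (log2 −1.10, edgeR adjusted p = 0.00111), while the iron list was not called, with 7 of 32 members higher and 6 lower (median log2 0.17, camera adjusted p = 0.329).

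Chaperones did not rise as a group in FBXL5ΔDC livers. Of 18 heat shock genes, 2 rose and 4 fell by either adjustment (median log2 −0.30, camera adjusted p = 0.430), and 0 to 2 fell with 1 library left out. Hspb8, a small heat shock protein, rose from 148 ± 24.5 to 562 ± 119 CPM (log2 1.92, edgeR adjusted p = 1.27e-04), whereas Dnajb1 went from 43.6 ± 14.1 to 19.6 ± 7.70 CPM without a call (edgeR adjusted p = 0.133). Of 23 genes of the integrated stress and unfolded protein response, 8 rose and 3 fell, and 8 rose and 5 fell over the list alone (median log2 0.26, camera adjusted p = 0.119). Ddit3 was at 6.80 ± 2.25 CPM before and 4.598 ± 0.838 CPM after acetaminophen (log2 −0.56, edgeR adjusted p = 0.237). Atf3 did rise, from 1.03 ± 0.654 to 66.7 ± 52.4 CPM (log2 6.01, edgeR adjusted p = 7.58e-04). Of 30 PPARα and fatty acid oxidation genes, 2 rose and 6 fell by either adjustment, without a call of the list (median log2 −0.02, camera adjusted p = 0.140).

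Immune, stromal and endothelial genes rose in treated FBXL5ΔDC livers. Of 32 cytokines, chemokines and adhesion genes, 16 rose and 1 fell, and 17 rose and 1 fell over the list alone (median log2 2.14, camera adjusted p = 1.57e-07, but 0.0733 with an estimated correlation). Of 32 interferon-stimulated genes, 17 rose and 1 fell, and 19 rose and 2 fell over the list alone (median log2 1.23, camera adjusted p = 5.63e-06, but 0.230 with an estimated correlation). Cxcl10 (ENSMUSG00000034855.13, chromosome 5 from 92346638 to 92348889), an interferon-induced chemokine for T cells, rose from 2.13 ± 0.368 to 68.2 ± 10.8 CPM (log2 4.999, SE 0.67, edgeR adjusted p = 5.58e-04). Of 15 neutrophil markers, 9 rose, and 11 over the list alone (median log2 4.28, camera adjusted p = 5.97e-04, but 0.0867 with an estimated correlation). Trem1, an activating receptor of neutrophils, went from 0 counts to 1.34 ± 0.425 CPM, at least 7.65-fold above the floor (edgeR adjusted p = 0.00480). Of 25 Kupffer cell genes, 12 rose and 2 fell, and 14 rose and 2 fell over the list alone (median log2 0.69, camera adjusted p = 5.97e-04, but 0.230 with an estimated correlation). Of 27 stellate cell and fibroblast genes, 15 rose and 1 fell, and 18 rose and 1 fell over the list alone (median log2 1.43, camera adjusted p = 6.85e-07, but 0.205 with an estimated correlation). Of 25 genes of the sinusoidal endothelium, 14 rose, and 15 over the list alone (median log2 0.74, camera adjusted p = 2.23e-05, but 0.339 with an estimated correlation). Of 30 acute phase genes, 11 rose and 3 fell, and 12 rose and 4 fell over the list alone (median log2 0.27, camera adjusted p = 0.0237, but 0.549 with an estimated correlation). Of 15 mitochondrially encoded transcripts, 10 rose and 1 fell, and 11 rose and 1 fell over the list alone (median log2 0.51, camera adjusted p = 0.00820, but 0.549 with an estimated correlation). Without 1 library, the numbers that rose were 4 to 10 for mitochondrial transcripts, 4 to 6 for neutrophil markers and 6 to 12 for Kupffer cell genes.

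FBXL5ΔDC livers at 6 h were compared with FBXL5ΔDC livers at 0 h to ask how acetaminophen acts when FBXL5 is deleted in Cd11c-expressing cells. The edgeR test called 2638 genes higher and 2648 lower, with 1694 and 1367 changed at least 2-fold. By unadjusted p, 7097 genes were below 0.05, and 48.8% of genes had non-overlapping libraries, against 10% by chance. Every alternative kept both counts within 1.5 times of these values, and with each library left out in turn 1849 to 2219 genes were higher and 1960 to 2292 lower.

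The responses of both genotypes were similar in direction. Glul fell in each genotype, and Hspb8, Hmox1, Gclc and Klf6 rose in each. Of the 1118 genes that rose in control livers, 860 (76.9%) also rose in FBXL5ΔDC livers, where 168 would be shared if the responses were independent, and 7 fell. Of the 739 genes that fell in control livers, 554 (74.97%) also fell in FBXL5ΔDC livers against 111 for independent responses, and 2 rose. The comparisons share no libraries, but they share the dispersion of each gene, which was fitted over all groups. Genes with a small dispersion are more easily called in both, so the numbers for independent responses may be too low. Across all 17585 genes the log2 changes correlated with r = 0.480, and across the 9392 genes with a mean of at least 2 log2 CPM with r = 0.760. Without control 6 h replicate 3 the first correlation was 0.302, and over all libraries left out in turn it ran up to 0.503.

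Untreated livers of the 2 genotypes differed in no gene at the threshold. The complement gene C9 (ENSMUSG00000022149.18, chromosome 15 from 6445327 to 6498751), whose product is made by hepatocytes, had the smallest p. Its abundance was 292 ± 10.9 CPM in control and 557 ± 26.8 CPM in FBXL5ΔDC livers (log2 0.93, SE 0.14, edgeR adjusted p = 0.333). G0s2, an inhibitor of fat breakdown that varies with feeding, was at 195 ± 60.7 and 63.3 ± 8.72 CPM (log2 −1.62, SE 0.39, edgeR adjusted p = 1). The protease inhibitor gene Serpina1e was at 4293 ± 618 and 8609 ± 984 CPM (log2 1.004, SE 0.22, edgeR adjusted p = 1), and it belongs to a family of near copies among which counts are hard to divide.

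No member of any list was called at 0 h by either adjustment. The fixed correlation of camera called 12 lists, and the lowest adjusted p with an estimated correlation was 0.540 over all 35 lists. By camera with the fixed correlation the highest-ranked list was acute phase proteins (median log2 0.33, adjusted p = 3.61e-08, but 0.540 with an estimated correlation). Red blood cell genes followed (median log2 0.46, camera adjusted p = 1.88e-05, but 0.540 with an estimated correlation). Stellate cell and fibroblast genes were lower (median log2 −0.31, camera adjusted p = 4.98e-05, but 0.611 with an estimated correlation). Mitochondrially encoded transcripts had a median log2 of 0.22 (camera adjusted p = 2.36e-04, but 0.611 with an estimated correlation). For Kupffer cells the median was 0.22 (camera adjusted p = 3.82e-04, but 0.540 with an estimated correlation), and for coagulation and fibrinolysis it was 0.21 (camera adjusted p = 4.5e-04, but 0.611 with an estimated correlation). The other 6 lists had camera adjusted p-values from 0.00866 for phase 1 enzymes to 0.0337 for heat shock genes, and 0.540 or more with an estimated correlation.

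The comparison of untreated livers asked whether the deletion alters the liver before injury. The edgeR test called 0 genes, with 465 genes below an unadjusted p of 0.05 (214 higher, 251 lower) and 11.7% of genes with non-overlapping libraries, against 10% by chance. DESeq2 called 8 genes higher and 6 lower, limma-voom called 1 higher, and a fit to the 2 groups alone called 3 higher. In simulated data 32% of 2-fold changes were recovered, for genes above a minimum abundance and with a spread shared by all 4 groups. Untreated livers varied less (median SD 0.250 and 0.216) than treated control livers (0.426), so that share is a rough guide only. Many differences of this size and below may have been missed.

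Treated livers of the 2 genotypes differed most in chaperone and pericentral genes, which were lower in FBXL5ΔDC livers. Dnajb1 was at 554 ± 346 CPM in control and 19.6 ± 7.70 CPM in FBXL5ΔDC livers (log2 −4.82, SE 0.62, edgeR adjusted p = 0.00469). Ddit3 was at 89.3 ± 29.9 and 4.598 ± 0.838 CPM (log2 −4.28, SE 0.38, edgeR adjusted p = 8.26e-04). Oat was at 300.2 ± 134 and 36.3 ± 7.34 CPM (log2 −3.05, SE 0.35, edgeR adjusted p = 0.00365). Cyp2e1 was at 3511 ± 1007 and 843 ± 292 CPM (log2 −2.06, SE 0.25, edgeR adjusted p = 0.00365), whereas Glul was alike at 99.03 ± 45.2 and 125 ± 13.6 CPM (log2 0.33, edgeR adjusted p = 0.491).

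Of 25 pericentral genes, 17 were lower over all genes and 18 over the list alone (median log2 −1.77, camera adjusted p = 2.38e-24, but 0.0972 with an estimated correlation). Of 18 heat shock genes, 14 were lower over all genes and 15 over the list alone (median log2 −1.92, camera adjusted p = 1.81e-21, but 0.128 with an estimated correlation). Hsp90aa1, an inducible cytosolic chaperone, was at 1552 ± 715 and 301 ± 43.7 CPM (log2 −2.36, edgeR adjusted p = 0.00535). Of 23 genes of the integrated stress and unfolded protein response, 8 were lower, and 14 over the list alone (median log2 −1.03, camera adjusted p = 2.92e-08, but 0.128 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, was at 1806 ± 266 and 859 ± 158 CPM (log2 −1.07, edgeR adjusted p = 0.0209). Of 20 phase 1 enzymes, 5 were lower and 1 higher, and 6 lower and 2 higher over the list alone (median log2 −0.20, camera adjusted p = 9.38e-04, but 0.128 with an estimated correlation). Cyp2a5, a cytochrome P450 induced by stress, was at 914 ± 507 and 28.3 ± 17.1 CPM (log2 −5.01, SE 0.70, edgeR adjusted p = 0.00665). Of 24 bile acid genes, 4 were lower, and 8 lower and 1 higher over the list alone (median log2 −0.34, camera adjusted p = 0.0161, but 0.237 with an estimated correlation). Periportal genes were higher in FBXL5ΔDC livers, with 4 of 24 members by either adjustment (median log2 0.40, camera adjusted p = 1.23e-05, but 0.128 with an estimated correlation). With each treated library left out in turn, 12 to 18 pericentral, 7 to 15 heat shock, 2 to 11 integrated stress and 0 to 11 bile acid genes were lower, and 0 to 7 periportal genes were higher. Medians of these lists kept their direction, whereas that of phase 1 enzymes ran from −0.53 to −0.01 and all but vanished without control replicate 3. A fit to the 2 groups alone called far fewer members. It had 1 pericentral, 0 heat shock, 1 integrated stress and 1 phase 1 gene lower, and 0 periportal genes higher. Its medians were −1.76 for pericentral and −1.92 for heat shock genes.

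**Figure D3:**
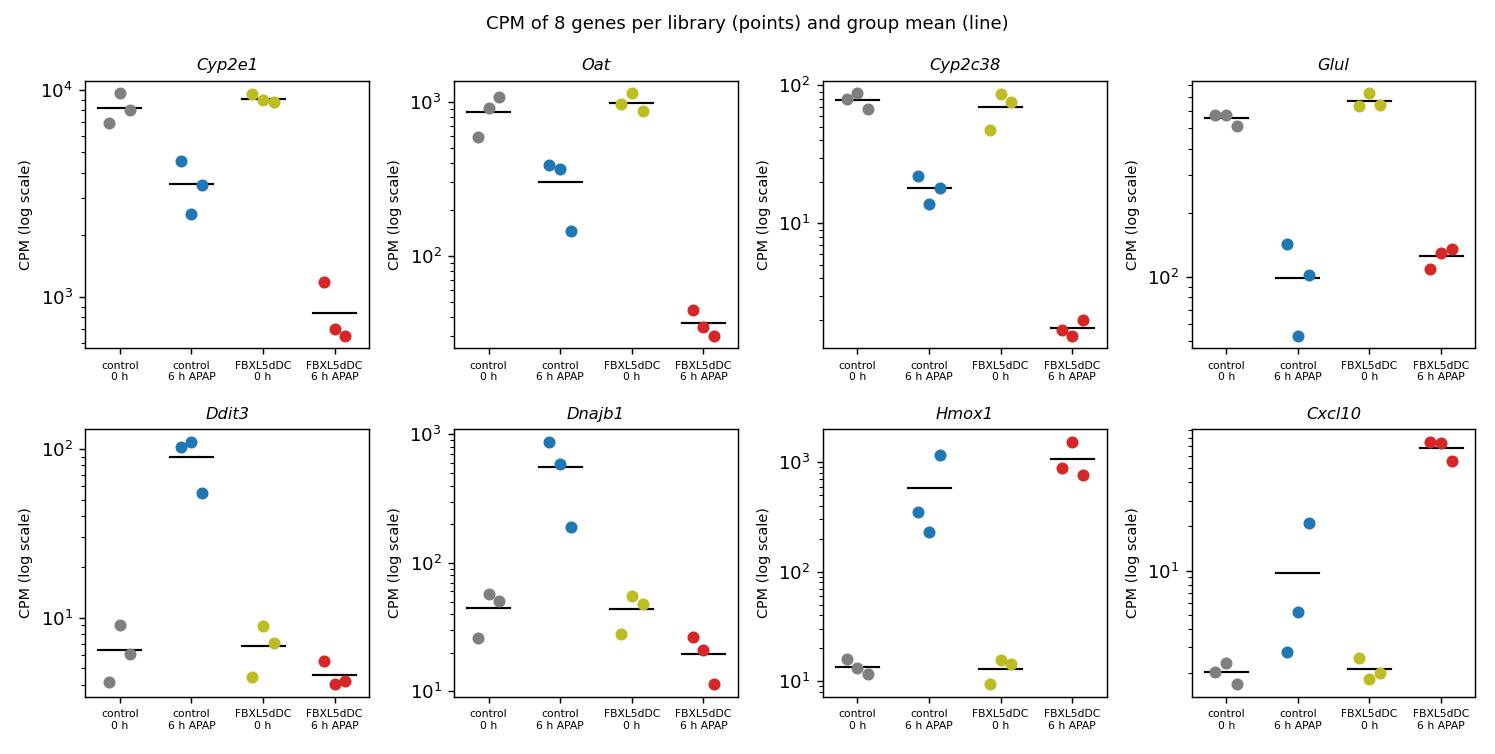
Abundance in CPM on a log axis of Cyp2e1, Oat, Cyp2c38, Glul, Ddit3, Dnajb1, Hmox1 and Cxcl10 in the 4 groups, with points for libraries and a line at the group mean. At 6 h Ddit3 was at 89.3 CPM in control and 4.598 CPM in FBXL5ΔDC livers, while Glul was at 99.03 and 125 CPM.

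Inflammatory, endothelial and mitochondrially encoded genes were higher in treated FBXL5ΔDC livers. Cxcl10 was at 9.70 ± 9.95 CPM in control and 68.2 ± 10.8 CPM in FBXL5ΔDC livers (log2 2.82, SE 0.60, edgeR adjusted p = 0.0253), with 2.77, 5.23 and 21.1 CPM in control replicates 1, 2 and 3. Socs3, which limits cytokine signalling, was at 18.1 ± 13.5 and 80.4 ± 15.1 CPM (log2 2.15, edgeR adjusted p = 0.0160). Irf8 (ENSMUSG00000041515.10, chromosome 8 from 120736358 to 120756694), a transcription factor of dendritic cells and monocytes, was at 6.22 ± 1.22 and 19.9 ± 3.96 CPM (log2 1.68, SE 0.26, edgeR adjusted p = 0.00553). Of 32 interferon-stimulated genes, 6 were higher, and 10 higher and 2 lower over the list alone (median log2 0.69, camera adjusted p = 1.51e-06, but 0.213 with an estimated correlation). Of 32 cytokines, chemokines and adhesion genes, 2 were higher, and 3 over the list alone (median log2 0.58, camera adjusted p = 6.31e-04, but 0.179 with an estimated correlation). Of 25 genes of the sinusoidal endothelium, 5 were higher, and 14 over the list alone (median log2 0.82, camera adjusted p = 4.47e-09, but 0.213 with an estimated correlation). The scavenger receptor gene Stab2 of those cells was at 25.8 ± 7.38 and 52.4 ± 9.40 CPM (log2 1.02, edgeR adjusted p = 0.0147). Of 15 mitochondrially encoded transcripts, 10 were higher, and 13 higher and 1 lower over the list alone (median log2 0.63, camera adjusted p = 1.32e-09, but 0.213 with an estimated correlation). Of 30 PPARα and fatty acid oxidation genes, 4 were higher and 2 lower, and 17 higher and 2 lower over the list alone (median log2 0.49, camera adjusted p = 1.64e-05, but 0.325 with an estimated correlation). Ehhadh, a peroxisomal enzyme of fatty acid oxidation, was at 1154 ± 211 and 2357 ± 268 CPM (log2 1.03, edgeR adjusted p = 0.0117). Single libraries moved the numbers of higher members, to 1 to 11 interferon-stimulated, 0 to 8 cytokine, 0 to 14 endothelial, 1 to 12 mitochondrial and 1 to 19 PPARα genes, while the medians stayed positive. A fit to the 2 groups alone called 0 interferon-stimulated, 0 endothelial and 0 mitochondrial genes higher.

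Differences at 6 h also concerned plasma proteins and non-parenchymal cells. Of 27 coagulation and fibrinolysis genes, 1 was higher, and 5 over the list alone (median log2 0.34, camera adjusted p = 3.56e-05, but 0.214 with an estimated correlation). Of 30 acute phase genes, 2 were higher and 1 lower, and 11 higher and 3 lower over the list alone (median log2 0.46, camera adjusted p = 1.53e-04, but 0.315 with an estimated correlation). Of 27 stellate cell and fibroblast genes, 2 were higher and 1 lower, and 4 higher and 1 lower over the list alone (median log2 0.67, camera adjusted p = 1.53e-04, but 0.304 with an estimated correlation). Of 25 Kupffer cell genes, 3 were higher and 2 lower, and 7 higher and 2 lower over the list alone (median log2 0.48, camera adjusted p = 3.58e-04, but 0.213 with an estimated correlation). Of 30 cell death genes, 1 was higher and 1 lower by either adjustment (median log2 0.28, camera adjusted p = 0.0226, but 0.213 with an estimated correlation). Without any member called, the lists of neutrophils (median log2 1.18, camera adjusted p = 0.00259, but 0.128 with an estimated correlation) and of cholangiocytes (median log2 0.90, camera adjusted p = 0.00532, but 0.213 with an estimated correlation) were higher. Leaving out libraries gave 0 to 13 higher coagulation, 0 to 12 acute phase, 0 to 11 stellate, 0 to 9 Kupffer and 0 to 10 cell death genes, and the upper values came without control replicate 3. Part of these differences was present before acetaminophen, with 0 h medians of 0.33 for acute phase, 0.21 for coagulation and 0.22 for Kupffer cell genes. The interaction medians of the same lists were 0.06, 0.13 and 0.21, without a call of the lists. The dendritic cell list, which holds the cell type targeted by the deletion, was not called (median log2 0.48, camera adjusted p = 0.0853), and Irf8 was its 1 higher member. The lists of iron genes (median log2 0.07, camera adjusted p = 0.787), ferroptosis (camera adjusted p = 0.408) and NRF2 targets (camera adjusted p = 0.297) were not called, although Ireb2 was lower at 66.7 ± 17.5 and 40.4 ± 8.60 CPM (log2 −0.72, edgeR adjusted p = 0.0388).

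**Figure D4:**
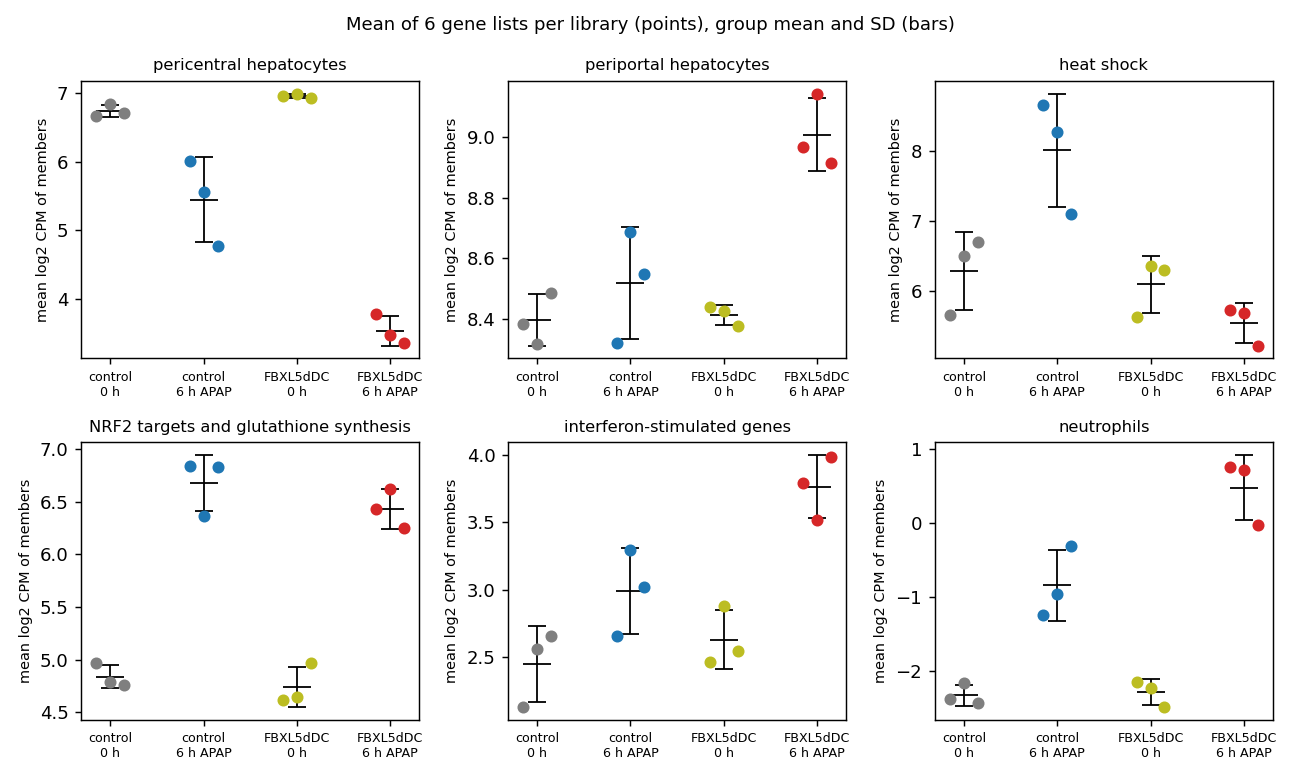
Mean log2 CPM of the members of 6 gene lists in each library (points), with the group mean ± SD (bar). The heat shock list was at 8.01 ± 0.81 in treated control and 5.54 ± 0.28 in treated FBXL5ΔDC livers, and the pericentral list at 5.45 ± 0.62 and 3.54 ± 0.22.

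Treated FBXL5ΔDC livers were compared with treated control livers to ask whether the deletion alters the outcome of acetaminophen. The edgeR test called 238 genes higher and 793 lower, with 126 and 451 changed at least 2-fold, and 3998 genes were below an unadjusted p of 0.05. Libraries did not overlap for 21.0% of genes, against 10% by chance. The counts depended on control replicate 3, without which 1873 genes were higher and 2376 lower, whereas without control replicate 1 they were 35 and 215, without control replicate 2 they were 49 and 254, and without single FBXL5ΔDC libraries they were 54 to 124 and 242 to 482. A fit to the 2 groups alone called 0 higher and 6 lower, DESeq2 called 741 and 1402, and limma-voom called 1909 and 2060. The main fit took its spread from all 4 groups, and untreated livers varied less (median SD 0.250 and 0.216) than treated control livers (0.426).

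The interaction, which asks whether acetaminophen acted differently in the genotypes, picked out pericentral genes and single stress genes. Cyp2c38 fell from 78.4 ± 10.3 to 18.0 ± 4.09 CPM in control livers and from 69.8 ± 20.3 to 1.74 ± 0.247 CPM in FBXL5ΔDC livers (log2 difference −3.20, SE 0.32, edgeR adjusted p = 0.00459). Oat had an interaction of −3.25 (SE 0.47, edgeR adjusted p = 0.0293), and Cyp1a2, which oxidises acetaminophen, one of −2.26 (SE 0.32, edgeR adjusted p = 0.0293). Ddit3 rose in control livers only, with an interaction of −4.36 (SE 0.49, edgeR adjusted p = 0.0114). For Dnajb1 the interaction was −4.78 (SE 0.78, edgeR adjusted p = 0.0483), and for Jun it was −3.17 (SE 0.53, edgeR adjusted p = 0.0465). Pparg, a regulator of lipid storage, was at 9.28 ± 1.30 and 9.90 ± 3.72 CPM in control livers and at 8.22 ± 1.28 and 1.46 ± 0.460 CPM in FBXL5ΔDC livers (log2 difference −2.58, edgeR adjusted p = 0.0386). Plin5, a coat protein of lipid droplets, was at 124 ± 31.4 and 51.9 ± 3.39 CPM in control livers and at 88.6 ± 7.88 and 108 ± 24.9 CPM in FBXL5ΔDC livers (log2 difference 1.54, edgeR adjusted p = 0.0483).

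Of 25 pericentral genes, 7 had a lower response in FBXL5ΔDC livers over all genes and 18 over the list alone (median log2 −1.88, camera adjusted p = 3.39e-27, but 0.0651 with an estimated correlation). Of 18 heat shock genes, 1 had a lower response over all genes and 15 over the list alone (median log2 −1.62, camera adjusted p = 2.23e-15, but 0.289 with an estimated correlation). Of 20 phase 1 enzymes, 3 had a lower response, and 5 over the list alone (median log2 −0.38, camera adjusted p = 1.82e-05, but 0.111 with an estimated correlation). Of 23 genes of the integrated stress and unfolded protein response, 1 had a lower response, and 8 lower and 1 higher over the list alone (median log2 −1.05, camera adjusted p = 1.82e-05, but 0.289 with an estimated correlation). Among 7 lists with a higher response, all without a called member over all genes, were those of stellate cells (median log2 0.94, 8 higher over the list alone, camera adjusted p = 2.63e-07, but 0.330 with an estimated correlation) and PPARα targets (median log2 0.56, 5 higher and 1 lower over the list alone, camera adjusted p = 5.66e-07, but 0.385 with an estimated correlation). Called members depended on single libraries, and leaving out 1 gave 0 to 18 lower pericentral, 0 to 14 heat shock, 0 to 6 phase 1 and 0 to 7 integrated stress genes, and 0 to 10 higher stellate and 0 to 13 higher PPARα genes. Glul (interaction 0.07, edgeR adjusted p = 0.966) and Fbxl5 (interaction 0.46, edgeR adjusted p = 0.635) had no detectable interaction.

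The edgeR test of the interaction called 6 genes higher and 45 lower, and 2543 genes were below an unadjusted p of 0.05 (914 higher, 1629 lower). Single libraries set these counts, which were 1103 and 1430 without control 6 h replicate 3, and fell to 0 to 4 higher and 1 to 18 lower when another library was left out. DESeq2 called 213 higher and 473 lower, limma-voom called 975 and 1239, and upper quartile scaling called 2 and 18.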

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

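The regroupings and the tests of explanations in this part were chosen only after the results were seen. The interaction, set before the data were examined, was the test of whether genotypes answered acetaminophen differently, and genes and lists with a different response stood out because that test put them past the threshold. The position of control 6 h replicate 3 passed no such threshold and is weighed because of its place on the first principal component. It called 6 genes higher and 45 lower in FBXL5ΔDC than in control livers. Among genes with a higher response were Mpzl1 (log2 1.76), Nt5c2 (1.73), Plin5 (1.54) and Peg3 (1.52). Pericentral and drug-metabolising genes with a lower response were Oat (−3.25), Cyp2c38 (−3.20), Gulo (−2.29), Cyp1a2 (−2.26), Cyp2e1 (−2.21, or −2.205 before rounding) and Cyp2c29 (−1.96). Stress genes with a lower response were Dnajb1 (−4.78), Ddit3 (−4.36) and Jun (−3.17). Others with a lower response were Lhpp (−3.38), Fam222a (−3.16), Pparg (−2.58) and Lor (−2.54). The transporter genes Slc13a3 (−9.36) and Slc1a2 (−7.26) had 0 counts and abundance below the floor in treated FBXL5ΔDC livers, so their fitted values are not bounds on the size of the difference.

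Gene lists with a lower median response in FBXL5ΔDC livers were pericentral hepatocytes (−1.88), heat shock (−1.62), integrated stress and unfolded protein response (−1.05), red blood cells (−0.78), bile acid synthesis and transport (−0.41) and phase 1 enzymes (−0.38). Lists with a higher median response were stellate cells and fibroblasts (0.94), PPARα targets and fatty acid oxidation (0.56), sinusoidal endothelium (0.57), interferon-stimulated genes (0.51), mitochondrially encoded transcripts (0.46), periportal hepatocytes (0.35) and cytokines, chemokines and adhesion (0.32). These 13 lists passed with the fixed correlation of camera, and 0 passed with an estimated correlation. With 1 library left out their medians kept their sign but moved. They ran from 0.14 to 0.73 for cytokines, 0.23 to 0.61 for interferon-stimulated genes, −0.52 to −0.24 for bile acid genes and −0.44 to −0.22 for phase 1 enzymes. When groups were redrawn 100 times, the real grouping and 2 others gave 51 or more genes, up to 82, and both others kept the treated groups as labelled. Only 15 of the groupings kept them, which is too few for a share under 0.05, and the other 85 gave 2 genes at most. For the number of lists, 38 of the 100 groupings reached 13, up to 21, so chance was not excluded for that number.

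The other contrasts allowed only 10 groupings of their libraries, too few for a share under 0.05 even where the real grouping ranked highest. In control livers acetaminophen gave 1857 genes and 21 lists in the real grouping, and 1 gene and 17 lists at most in another. In FBXL5ΔDC livers it gave 5286 genes and 18 lists, and 0 genes and 17 lists at most in another. Genotype at 6 h gave 1031 genes and 18 lists, and 1 gene and 19 lists at most in another. Genotype at 0 h gave 0 genes and 12 lists, and 1 gene and 14 lists at most in another. For both genotype contrasts 3 of the 10 groupings, the real one included, reached the real number of lists, so chance was not excluded for these numbers.

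Control 6 h replicate 3 lay near the treated FBXL5ΔDC libraries. Its total of 68.8 M counts lay within the range of the other libraries (67.2 to 72.5 M), which argues against library size. A swapped label was tested with genes that separate the genotypes in the other 11 libraries. The first version used all 179 such genes, of which 49 (27.4%) put this library on the control side, the lowest share of the 12 libraries, where others had 39.8% to 78.3%. After that was seen, the test was restricted to 86 genes with little response to acetaminophen, and 33 of them (38.4%) put it on the control side, where others had 35.6% to 81.3%. Some other measures, picked after the results were seen, set it apart from the treated FBXL5ΔDC libraries. Its heat shock list mean was 7.10 log2 CPM, where those had 5.22 to 5.72 and the other treated controls 8.26 and 8.66. Its integrated stress list mean was 5.53, where those had 4.41 to 4.76. Its pericentral list mean was 4.78, where those had 3.36 to 3.78 and the other treated controls 5.56 and 6.00. Mitochondrial genes held 7.05% of its counts, against 8.94% to 9.43% in those. Other measures, picked likewise, put it among or near those libraries. Its acute phase list mean was 8.32, where those had 8.25 to 8.42 and the other treated controls 7.46 and 7.56. Its circadian clock list mean was 3.85, where those had 3.83 to 3.97 and the other treated controls 4.36 and 4.38. Chi-square per degree of freedom was 51.1 to 60.7 between it and those, against 127 and 128 between it and the other treated controls. Neither version could decide on a swapped label. Both put the other 11 libraries on their own side poorly, with medians of 51.5% in the first and 63.8% in the second. The list means went both ways and leave a swapped label open. A control liver with more advanced injury was not tested.

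Pericentral genes were lower in treated FBXL5ΔDC than in treated control livers. A single scaling error per library would move both hepatocyte zones alike, but the pericentral minus periportal list mean differed by −2.40 log2 (SE 0.44), which argues against it. A smaller share of hepatocyte RNA would lower periportal genes too, and these were higher by 0.49 (SE 0.13). Control 6 h replicate 3 was the treated control nearest to the treated FBXL5ΔDC libraries, with a pericentral list mean of 4.78 against 5.56 and 6.00. That library thus narrowed the difference. Leaving it out was bound to widen the median, from −1.77 to −1.96, and so was no test of an explanation. The tests leave loss or dedifferentiation of pericentral hepatocytes, a later stage of injury and a difference in dose as explanations that these data could not tell apart.

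Interferon-stimulated genes were higher in treated FBXL5ΔDC livers by a median of 0.69 log2. More leukocytes in the tissue would raise leukocyte markers too, and the 58 such markers with a mean of at least 1 CPM had a median of 0.49 (SD 0.55). Medians of the whole leukocyte lists ran from −0.12 for monocytes and infiltrating macrophages to 1.18 for neutrophils. The test therefore left open whether the genes rose within cells or came with additional cells.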

How the results depend on the processing

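No called gene or list was called in the opposite direction under any alternative, and counts of the FBXL5ΔDC response stayed within 1.5 times of their values throughout. Uncalled differences of Fbxl5 and Itgax did change sign, and upper quartile factors turned the balance of rises and falls in control livers to 911 and 938. Division of the counts by 4 and removal of mitochondrial genes were added after the data were seen, and all other alternatives were set before. The cause of the differences below was not tested. Fits to 2 groups or without a library rest on fewer samples, but this alone does not account for them. The fit to the FBXL5ΔDC groups alone called 3016 genes higher and 2987 lower, more than the 2638 and 2648 of the main fit. The main fit shared 1 dispersion per gene over groups of unequal spread (median SD of log2 CPM 0.216 to 0.426). DESeq2 called 1687 genes higher and 1196 lower for acetaminophen in control livers, 8 and 6 for genotype at 0 h, 741 and 1402 at 6 h, and 213 and 473 for the interaction. With limma-voom and sample weights the counts were 1 and 0 at 0 h, 1909 and 2060 at 6 h, and 975 and 1239 for the interaction. Fits to the compared groups alone gave 235 and 167 for acetaminophen in control livers, 3 and 0 at 0 h, and 0 and 6 at 6 h. Upper quartile factors gave 2 and 18 for the interaction. Counts divided by 4 gave 28 lower genes for the interaction. With the replicate block it had 24 lower genes, and this block was not used for the results because replicate numbers did not pair libraries, since 18 pairs of libraries with the same number had correlations of −0.061 to 0.044 and 0 exceeded 0.1.

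With each library left out in turn, acetaminophen in control livers gave 449 to 1361 genes higher and 314 to 809 lower. Genotype at 6 h gave 35 to 1873 higher and 215 to 2376 lower, with the upper values without control replicate 3. The interaction gave 0 to 1103 higher and 1 to 1430 lower, again with the upper values without that library. Nearly all original calls lay within those larger sets, with 1029 of 1031 genes at 6 h and 51 of 51 for the interaction. Control replicate 3 was the treated control nearest to the treated FBXL5ΔDC libraries, so this overlap does not show that the calls are stable. Leaving out any other treated library kept 244 to 481 of the 1031 calls at 6 h. Leaving out any other library kept 1 to 20 of the 51 for the interaction. The fit to the 2 groups alone kept 6 of the 1031. The correlation of the responses was 0.760 for abundant genes, and over all genes it ran from 0.302 to 0.503 with libraries left out. Named genes kept their call under every alternative in 17 of 20 cases for acetaminophen in each genotype, in 0 of 20 at 6 h and in 1 of 14 for the interaction, which was Cyp2c38. Camera with the fixed correlation called 21 and 18 of the 35 lists for acetaminophen in control and FBXL5ΔDC livers. It called 12 and 18 for genotype at 0 h and 6 h, and 13 for the interaction. With an estimated correlation 3, 2, 0, 0 and 0 lists were called, in the same order. Among the 175 list tests this took the call from 77, fry from 29 and the removal of shared members from 9. In turn fry added 6 and the block added 2. Depth limits genes near the floor of 12 counts, such as Itgax and many T and natural killer cell markers.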

Other observations

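Gene lists of metabolism and time of day had mixed members and were not called. Of 19 circadian clock genes, 3 rose and 1 fell with acetaminophen in control livers (median log2 0.67, camera adjusted p = 0.0887), and 5 rose and 6 fell in FBXL5ΔDC livers (camera adjusted p = 0.926), where the median was −0.48 but the mean was 0.06. With 1 library left out that median ran from −0.59 to 0.00. Adjusted over the list alone, 5 clock genes rose and 2 fell in control livers, and 7 rose and 6 fell in FBXL5ΔDC livers. Bhlhe41, a repressor of clock genes, rose from 0.797 ± 0.765 to 5.54 ± 1.78 CPM in control livers (log2 2.79, edgeR adjusted p = 0.00884) and from 0.421 ± 0.126 to 8.12 ± 2.25 CPM in FBXL5ΔDC livers (log2 4.26, edgeR adjusted p = 4.27e-04). Of 19 fatty acid synthesis genes, 3 rose and 6 fell in control livers (camera adjusted p = 0.370), and 5 rose and 5 fell in FBXL5ΔDC livers (camera adjusted p = 0.974). Adjusted over the list alone, 6 rose and 8 fell in control livers, and 6 rose and 5 fell in FBXL5ΔDC livers. Acacb, which slows fatty acid oxidation, fell in each (log2 −1.36 and −1.73). Of 19 gluconeogenesis and fasting genes, 2 rose and 2 fell by either adjustment in control livers (median log2 −0.20, camera adjusted p = 0.389), and 2 rose and 3 fell by either adjustment in FBXL5ΔDC livers (median log2 0.25, camera adjusted p = 0.691). Pck1, which makes the committed step of glucose synthesis, fell from 3872 ± 473 to 1885 ± 818 CPM in control livers (log2 −1.04, edgeR adjusted p = 0.0425) and from 4320 ± 178 to 1463 ± 445 CPM in FBXL5ΔDC livers (log2 −1.56, edgeR adjusted p = 0.00229). Coagulation genes were not called in either response (camera adjusted p = 0.762 and 0.204), with medians of −0.01 and −0.02 but means of 0.51 and 0.93. Over all genes, 2 of 27 rose and 3 fell in control livers, and 9 rose and 4 fell in FBXL5ΔDC livers, and over the list alone 3 rose and 4 fell, and 9 rose and 5 fell.

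Lists of proliferation and lymphocyte genes were not called in either response. Of 27 cell cycle genes, 3 rose in control livers (camera adjusted p = 0.432), and 4 rose and 2 fell in FBXL5ΔDC livers (camera adjusted p = 0.796), or 3 and 1 over the list alone. Of 24 T and natural killer cell markers, 0 were called in control livers (camera adjusted p = 0.365) and 2 rose in FBXL5ΔDC livers (camera adjusted p = 0.140), or 0 over the list alone. The medians of this list were 0.62 and 0.74 log2, with many markers near the floor. Of 18 B and plasma cell markers, 1 rose in each response (camera adjusted p = 0.445 and 0.608). Of 29 dendritic cell markers, 1 rose in control livers, or 0 over the list alone (camera adjusted p = 0.383), and 2 rose and 1 fell in FBXL5ΔDC livers (camera adjusted p = 0.168). The dendritic cell integrin gene Itgae fell below the floor there, at least 2.25-fold (edgeR adjusted p = 0.0197). Of 18 cholangiocyte genes, 3 rose in control livers (camera adjusted p = 0.276), and 8 rose and 3 fell in FBXL5ΔDC livers (camera adjusted p = 0.0684). Over the list alone, 3 rose and 1 fell in control livers, and 9 rose and 3 fell in FBXL5ΔDC livers. Sox9, a transcription factor of bile ducts and of reprogrammed hepatocytes, rose from 5.10 ± 1.84 to 111 ± 83.1 CPM in FBXL5ΔDC livers (log2 4.44, edgeR adjusted p = 7.52e-04). Of 9 red blood cell genes, 1 rose in control livers, or 4 over the list alone (camera adjusted p = 0.0757), and 1 fell in FBXL5ΔDC livers (camera adjusted p = 0.430).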
